A study of Mus musculus with 10 samples.

How the data were processed

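Hearts were taken from 9-week-old FVB/NJ mice, and the ventricular apex was frozen and its RNA extracted with Trizol, per the labels' protocols, which also call the tissue whole heart. Polyadenylated RNA was selected, fragmented chemically and made into single-end libraries that do not keep the strand, so reads of overlapping or antisense genes cannot be told apart. The titles of the TAC libraries name the operation and the week. Those of the other 5 libraries do not say sham, and their group comes from the series design text, which gives 5 female sham and 5 female TAC animals. That text counts mice, so the replicates are taken as separate animals, although no animal identifiers are given.

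The deposited table holds whole-number read counts per Ensembl gene for all 10 libraries, not normalized, made by the authors. The submitters' processing notes list Bowtie2, TopHat2 2.0.10, HTSeq and mm10 for the sham libraries and Bowtie, TopHat 1.3.0, HTSeq, mm9 and mm10 for the TAC libraries, and the header of the gene ID column names GRCm37 for all columns. Stated processing therefore differs between the groups and cannot be separated from them. The counter's settings and the annotation release are not given in the sources used here. If some reads were placed differently by these versions, counts of genes with many splice junctions or near copies would shift between groups. No gene was at 0 in all libraries of one group with at least 10 counts in each library of the other. A row of column totals, which names no gene and adds no counts of its own, was left out of library sizes and tests. All 10 sample columns were used. Within-group library pairs differed by a chi-square per gene of 2.67 to 24.9 over 20 pairs, far above sampling noise, so none was counted as a repeat of another.

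Gene symbols are those of the table. GENCODE M21 (GRCm38) was used for gene length, GC content and exon number, matched by Ensembl ID. Of the 20692 IDs, 94.6% matched. The depth of 7410967 to 10126574 counts per library limits what can be seen for weakly expressed genes, and 8691 genes were not tested.

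Differences were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) by quasi-likelihood F tests on the deposited counts, with TMM normalization, filterByExpr defaults (minimum count 10, minimum total 15), trended dispersion, group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. The 30 gene lists, 8 primary and 22 secondary, were fixed with the other planned choices before the data were examined. They cover cardiomyocyte functions (hypertrophic and fetal-type, adult sarcomere, calcium handling, ion channels), extracellular matrix, basement membrane, fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, mitochondrial regulators and mitochondrially encoded transcripts, markers of macrophages, fibroblasts, smooth muscle, endothelium, lymphocytes, neutrophils, erythroid cells, adipocytes, atrial cardiomyocytes and nerve or glia, and immediate early, endoplasmic reticulum stress, cell cycle, interferon, clock, ribosomal protein, nuclear non-coding and Y-linked genes. Of these, 27 had at least 3 tested members and were tested by camera with a preset inter-gene correlation of 0.01, adjusted over the 27 lists. That test called 17 lists, 8 up and 9 down. No call held with a correlation estimated for each list. The fry test, which asks only whether a list's genes move on balance one way and makes no comparison with other genes, was also run. Among the lists that camera called, the fry adjusted p lay between 7.50e-05 (basement membrane) and 0.0107 (calcium handling), apart from mitochondrially encoded transcripts (0.0528). Of the lists that camera did not call, it was under 0.05 for endoplasmic reticulum stress (0.0160) and nuclear-retained non-coding RNAs (0.0013).

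Genes were named by a fixed rule. It takes the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean log2 CPM of at least 1 and no overlap between groups, predicted genes and unnamed clones excepted (none had to be passed over), a fixed panel of 18 genes, up to 4 members of each list with the smallest adjusted p, and the genes of the hypotheses tested. Other list members, named to say which ones make up a small count, and members of gene families defined by symbol were chosen after their values were seen. A few genes that the rule or a list takes are not reported here by name, but they stay in all counts. Library distances and library values were compared by exact permutation tests over all 252 divisions of the 10 libraries into 5 and 5, so that the smallest p possible is 0.00794 for the distance.

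The method was tested on simulated data with the means, dispersions and library sizes of these 12001 genes, of which 200 were changed. It recovered 68.7% of genes changed 1.5-fold, 89.5% of those changed 2-fold and 98.5% of those changed 4-fold, and called 15 unchanged genes. The share of genes changed there was far below the 35.8% called in the data, so these rates may differ from those of the data. Simulated genes were drawn independently, so the list test was not tested there under correlation. Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, robust dispersion, no filter and another filter (CPM of at least 1 in 5 libraries), a replicate block, leaving out each library, a minimum fold of 1.5, removal of ribosomal protein, pseudogene and mitochondrial genes, a GC content and length correction, and an estimated list correlation. The other filter was planned as stricter but kept 12204 genes against 12001, so no filter stricter than the one used was run. Member counts of each list and the distance without the library labelled TAC replicate 1 were added after seeing the data. Figures were drawn with matplotlib.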

Results

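Polyadenylated RNA was sequenced from the ventricular apex of 10 hearts of 9-week-old FVB/NJ mice, an inbred laboratory strain, all labelled female. Of these libraries, 5 came from sham-operated animals and 5 from animals 1 week after transverse aortic constriction (TAC), a surgical narrowing of the aortic arch that raises the pressure load on the left ventricle. The comparison asks which cardiac transcripts change after 1 week of pressure overload. The table holds read counts for 20692 genes, of which 12001 had enough counts to be tested, and each library has between 7410967 and 10126574 counts. The mean total was 8929860 counts in sham and 8300250 in TAC (exact two-sided permutation test, p = 0.262). Values per group are mean CPM (counts scaled to a common library total) ± SD over 5 libraries, log2 fold changes are TAC over sham ± standard error (SE), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

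The sham and TAC hearts lay apart as wholes. Over the 1000 most variable genes, libraries of different groups lay a mean Euclidean distance of 41.5 apart on the log2 scale and libraries of the same group 23.1 apart. The difference of 18.4 was the largest over all 252 ways to divide the 10 libraries into 5 and 5 (exact permutation test, p = 0.00794, the smallest this design can give). The first principal component took 65.5% of the variance and separated the groups, with TAC libraries between 11.3 and 31.9 and sham libraries between -22.6 and -14.4. The library labelled TAC replicate 1 had the highest score, and it did not match its female label. It held 14 counts of Xist (ENSMUSG00000086503, the RNA that coats the inactive X chromosome of female cells), against 1042 to 1561 in the other 9 libraries. It held 155 counts of the Y-linked gene Ddx3y and 132 of Eif2s3y, where no other library had more than 2 of either. Member counts without it are given for the lists of the main functions below.

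**Figure D1:**
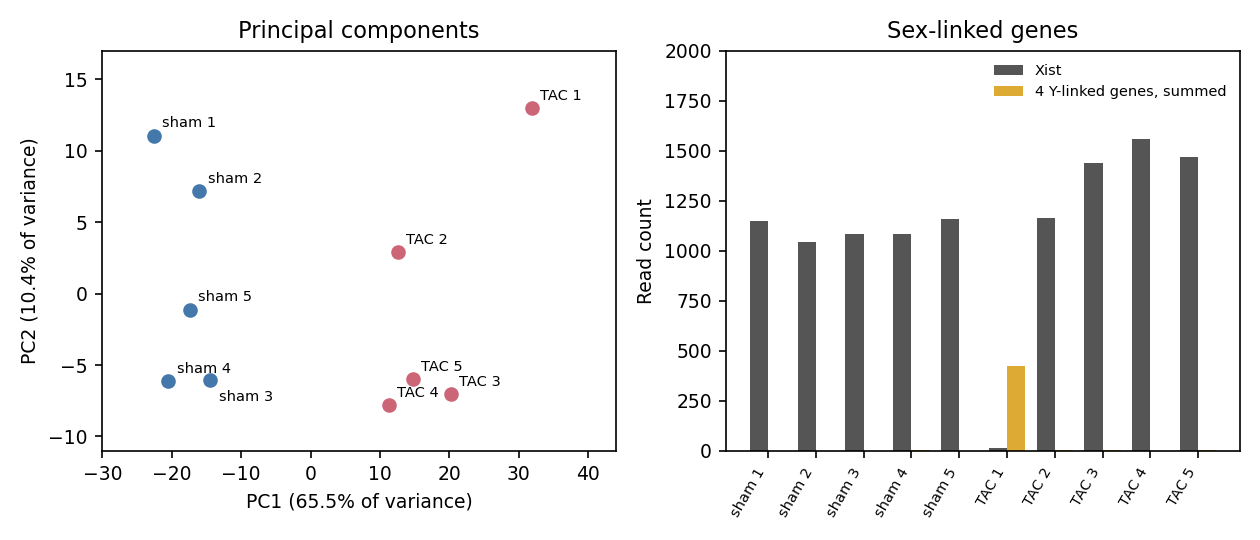
Left, the 10 libraries on the first and second principal components of the 1000 most variable genes (log2 CPM), with sham in blue and TAC in red. Right, read counts per library of Xist and of 4 Y-linked genes summed. The library labelled TAC replicate 1 has the highest first component, 31.9, and the lowest Xist count, 14, beside 425 Y-linked counts.

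TAC hearts differed from sham hearts over a large part of the transcriptome. Of 12001 tested genes, 2251 were higher and 2040 lower in TAC at an adjusted p under 0.05 by edgeR, together 35.8%. Most changes were small: the median fold of the called genes was 1.47 for those higher and 0.783 for those lower, and 390 genes rose and 43 fell by at least 2-fold. In 1461 genes all TAC libraries lay above all sham libraries and in 1389 all lay below, 23.7% of those tested, where chance alone gives 0.794%. Without the library labelled TAC replicate 1, 2020 genes were higher and 1822 lower, and 3686 of the called genes were called in the same direction. The split depended on scaling: with library totals in place of TMM factors, the median log2 fold change of all genes moved from 0.00 to 0.11, and 3257 genes were higher and 1159 lower, so that 73.8% of the calls were higher in place of 52.5%.

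Genes of cell division had the highest median change of the 27 lists tested. Of 28 tested cell cycle genes, 27 rose, none fell and 1, Cenpf, did not pass, with a median log2 fold change of 2.18. Adjusted over the list alone, 28 rose, and 27 rose without the library labelled TAC replicate 1. Mki67, whose product marks proliferating cells, went from 3.73 ± 2.73 to 39.7 ± 11.4 CPM (log2 fold change 3.44 ± 0.33, adjusted p = 2.73e-05 by edgeR). Prc1, which bundles microtubules of the central spindle, and Bub1b, a spindle checkpoint kinase, rose 10.1-fold and 9.97-fold. Plk1, a mitotic kinase, rose 6.67-fold, and Ccnd1, cyclin D1, which acts before DNA replication, 2.07-fold. The 12 genes with the largest rises include Kif18b, a mitotic kinesin, Anln, a scaffold of the cleavage furrow, Aurkb, a mitotic kinase, Ccna2, a cyclin, and Ckap2 and Ckap2l, with log2 fold changes of 3.80, 3.57, 3.56, 3.35, 3.77 and 3.46. Mxd3, a transcription factor of the Myc network, and Hist1h2ao, a histone gene with near-identical copies that may share its reads, had values of 3.52 and 3.44. In sham, Bub1b, Plk1, Kif18b, Anln, Aurkb, Ccna2, Ckap2, Ckap2l, Mxd3 and Hist1h2ao had mean levels of 0.265 to 0.722 CPM. Their folds thus rest on few sham reads, whereas Prc1 had 1.35 and Ccnd1 54.2 CPM in sham. The largest rise of the 12 was that of Col9a2, a chain of a fibril-associated collagen, from 0.215 ± 0.235 to 3.68 ± 0.628 CPM (log2 fold change 4.04 ± 0.40). Camera, which compares a list with all other genes, called the cell cycle list (adjusted p = 1.01e-36), but not with an estimated correlation between its genes (adjusted p = 0.126 with an estimated correlation).

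Genes of the extracellular matrix rose almost as a block. Of 55 tested matrix and matrix remodelling genes, 50 rose, none fell and 5 did not pass, with a median log2 fold change of 1.3. Those not passing include Timp3, Thbs1, Thbs2 and Plod2. Adjusted over the list alone, 51 rose; without the library labelled TAC replicate 1, 48 rose and 1, Thbs2, fell. Postn (ENSMUSG00000027750), which encodes periostin, a matricellular protein of activated fibroblasts, went from 21.5 ± 3.01 to 185 ± 76.5 CPM (log2 fold change 3.11 ± 0.24, adjusted p = 1.06e-05 by edgeR). Cilp, a cartilage-type matrix protein, Mfap4, a microfibril-associated protein, and Sparc, a collagen-binding matricellular protein, had log2 fold changes of 2.32 ± 0.20, 2.26 ± 0.21 and 1.27 ± 0.12. Col1a1 and Col3a1, which encode chains of fibrillar collagens, rose 4.4-fold and 4.35-fold. The library labelled TAC replicate 1 lay far above the rest in both, with Col1a1 at 2998 CPM against 825 to 1041 in the other TAC libraries, and without it the log2 fold change of Col1a1 was 1.61 in place of 2.14. Ctgf, a connective tissue growth factor, rose 2.13-fold. Timp1, an inhibitor of metalloproteinases, had a log2 fold change of 2.57 ± 0.76 with all libraries and 1.36 without that library, and its call ended with limma-voom (adjusted p = 0.117) and with robust dispersion estimates (adjusted p = 0.0665 by edgeR). Camera called the list (adjusted p = 5.19e-33), with adjusted p = 0.20 with an estimated correlation.

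Basement membrane genes rose with them. Of 15 tested, 13 rose, none fell and 2, Lama5 and Lamb2, did not pass (median log2 fold change 0.63), and 13 rose adjusted over the list alone. Nid2 and Nid1 encode nidogens, which link laminin and collagen networks. Nid2 went from 48.8 ± 2.55 to 110 ± 8.71 CPM (log2 fold change 1.18 ± 0.07, adjusted p = 1.26e-06 by edgeR), and Nid1 rose 1.72-fold. The laminin chains Lamc1 and Lamb1 rose 1.59-fold and 1.5-fold. Camera gave adjusted p = 1.29e-13, and adjusted p = 0.126 with an estimated correlation. Fibroblast markers moved in both directions: of 18 tested, 9 rose, 3 fell and 6 did not pass (median log2 fold change 0.34), and 11 rose and 3 fell adjusted over the list alone. Fstl1, a secreted glycoprotein, rose 2.71-fold, Meox1, a homeobox transcription factor, 2.69-fold and Mfap2 3.61-fold, while Scara5, Wif1 and Gsn fell. Camera called the fibroblast list up (adjusted p = 0.00111; adjusted p = 0.204 with an estimated correlation).

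Stress-responsive genes of cardiomyocytes rose. Of 20 tested hypertrophic and fetal-type genes, 14 rose, 2 (Tuba8 and Nebl) fell and 4 did not pass (median log2 fold change 0.90). Adjusted over the list alone, 15 rose and 2 fell, and without the library labelled TAC replicate 1, 13 rose and 1 fell. Nppa (ENSMUSG00000041616), which encodes atrial natriuretic peptide, went from 133 ± 35.8 to 741 ± 286 CPM (log2 fold change 2.48 ± 0.24, adjusted p = 2.71e-05 by edgeR). Nppb, brain natriuretic peptide, rose 2.62-fold. Acta1, skeletal alpha-actin, rose 3.64-fold, from 1232 ± 388 to 4482 ± 1442 CPM, and Ankrd1, a stress-induced ankyrin repeat protein of the sarcomere, 3.42-fold. Mybpc2, a myosin-binding protein, rose 2.65-fold and Synpo2l, a Z-disc protein, 2.71-fold. Myh7 (ENSMUSG00000053093), the beta myosin heavy chain, gave 4062 ± 356 CPM in sham and 4098 ± 550 CPM in TAC and did not pass (log2 fold change 0.01 ± 0.09, adjusted p = 0.932 by edgeR). Myh6 (ENSMUSG00000040752), the alpha chain that predominates in the adult mouse ventricle, fell from 42830 ± 4382 to 31778 ± 6938 CPM (log2 fold change -0.43 ± 0.14, adjusted p = 0.0335 by edgeR). These neighbouring genes have nearly alike coding sequences, so reads may be shared between them and both values are uncertain. The Myh6 call ended with library totals only (adjusted p = 0.0579 by edgeR) and in 4 of the 10 sets that left out a library. Camera called the hypertrophic list (adjusted p = 6.05e-08), with adjusted p = 0.263 with an estimated correlation.

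**Figure D2:**
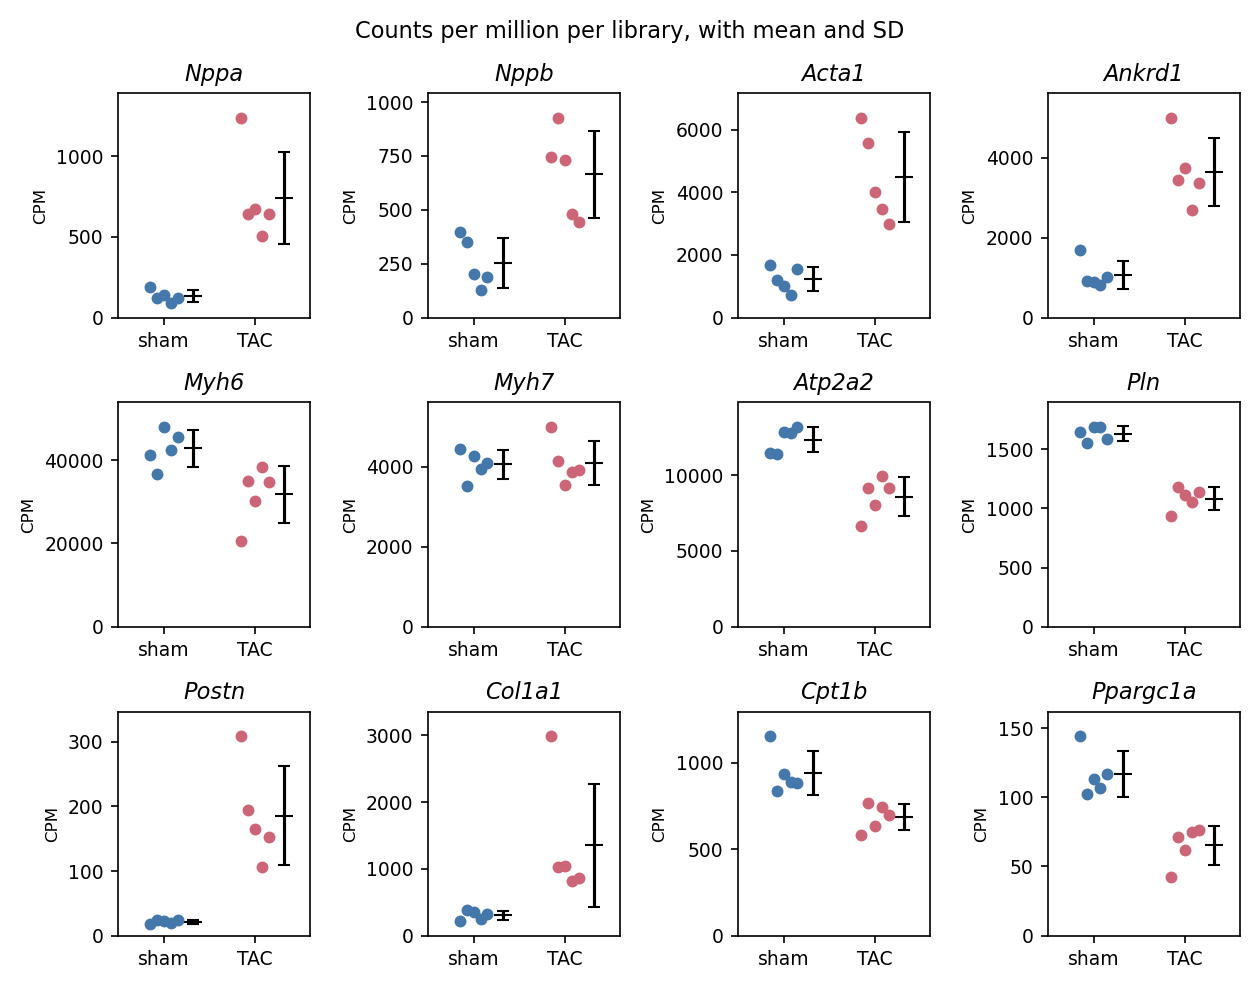
CPM per library of 12 genes of the fixed panel in sham (blue) and TAC (red), with the mean and SD of 5 libraries beside the points; every axis starts at 0. Nppa, Nppb, Acta1, Ankrd1, Postn and Col1a1 lie higher in every TAC library than in every sham library, Atp2a2, Pln, Cpt1b and Ppargc1a lie lower, and Myh6 and Myh7 overlap.

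Adult sarcomere genes fell. Of 20 tested, none rose, 12 fell and 8 did not pass (median log2 fold change -0.30). Adjusted over the list alone 12 fell, without the library labelled TAC replicate 1, 11 fell, and with library totals only 9 fell (median log2 fold change -0.20). Tnnt2 and Tnni3, cardiac troponins T and I, had log2 fold changes of -0.47 ± 0.06 and -0.60 ± 0.09. Mylk3, the kinase of cardiac myosin light chain, and Ldb3, a Z-disc protein, were at 0.683 and 0.749 of their sham level. This list had adjusted p = 2.04e-05 by camera, and adjusted p = 0.276 with an estimated correlation.

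Genes of calcium handling and of membrane excitation mostly fell where they changed. Of 20 tested calcium handling genes, 9 fell, 4 rose and 7 did not pass (median log2 fold change -0.20). Adjusted over the list alone 11 fell and 4 rose, without the library labelled TAC replicate 1, 9 fell and 4 rose, and with library totals only 7 fell and 4 rose (median log2 fold change -0.09). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 12347 ± 847 to 8581 ± 1270 CPM (log2 fold change -0.52 ± 0.10, adjusted p = 0.00158 by edgeR). Pln, phospholamban, which inhibits that pump, had a log2 fold change of -0.59 ± 0.07 (adjusted p = 5.65e-05 by edgeR). Jph2, junctophilin, which holds the reticulum near the cell membrane, and Cacna1c, the L-type calcium channel, were at 0.775 and 0.738 of their sham level. The members that rose include Atp2b4, a calcium pump of the cell membrane, Casq1, the calsequestrin of skeletal muscle, and Itpr1, a calcium release channel. By camera the adjusted p was 0.00431, and adjusted p = 0.385 with an estimated correlation. Of 22 tested ion channel genes, 13 fell, none rose and 9 did not pass (median log2 fold change -0.47), and adjusted over the list alone 13 fell and 1 rose. Without the library labelled TAC replicate 1, 12 fell and 1, Kcna5, rose. Kcnj11, Kcnk3, Kcnh2 and Kcnj2, which encode potassium channels, had log2 fold changes of -0.56, -0.51, -0.73 and -0.80. Kcnv2, a modifying potassium channel subunit, was among the 12 genes with the largest falls, at 0.432 of its sham level. Kcnip2, a subunit of the channels of the fast transient outward current, had a log2 fold change of -0.37 ± 0.13 (adjusted p = 0.0348 by edgeR), and its call ended with library totals only (adjusted p = 0.140 by edgeR) and in 7 of the 10 sets that left out a library. Camera gave adjusted p = 4.36e-06, and adjusted p = 0.204 with an estimated correlation.

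Genes of fatty acid oxidation, oxidative phosphorylation and the tricarboxylic acid cycle fell nearly without exception, and most regulators of mitochondrial gene expression fell. Of 32 tested fatty acid uptake and oxidation genes, 30 fell, none rose and 2, Pdk4 and Cpt1a, did not pass (median log2 fold change -0.60), and adjusted over the list alone 32 fell. Ech1, an enzyme of unsaturated fatty acid oxidation, was at 0.518 of its sham level, and Acadm, the medium-chain acyl-CoA dehydrogenase, fell from 869 ± 55.9 to 528 ± 69.8 CPM (log2 fold change -0.72 ± 0.09, adjusted p = 9.03e-05 by edgeR). Cpt1b, the muscle carnitine palmitoyltransferase that admits fatty acids to mitochondria, had a log2 fold change of -0.46 ± 0.10 (adjusted p = 0.00292 by edgeR). Of 78 nuclear-encoded oxidative phosphorylation genes, 76 fell, none rose and 2, Cox8a and Cox6a1, did not pass (median log2 fold change -0.39), and 77 fell adjusted over the list alone. Cox8b and Cox6a2, heart isoforms of cytochrome c oxidase subunits, were at 0.684 and 0.737 of their sham level. All 19 tested genes of the tricarboxylic acid cycle and pyruvate entry fell (median log2 fold change -0.39), both over all genes and adjusted over the list alone. Among them, Idh2, an isocitrate dehydrogenase, and Cs, citrate synthase, had log2 fold changes of -0.68 ± 0.07 and -0.43 ± 0.07. Of 21 regulators of mitochondrial gene expression, 13 fell, none rose and 8 did not pass (median log2 fold change -0.33), and adjusted over the list alone 14 fell and 1 rose. Ppargc1a, the coactivator PGC-1 alpha, fell from 117 ± 16.6 to 65.4 ± 14.1 CPM (log2 fold change -0.84 ± 0.14, adjusted p = 0.000724 by edgeR), and Rxrg, Esrra and Esrrb, which encode nuclear receptors, had log2 fold changes of -0.71, -0.43 and -0.49. Without the library labelled TAC replicate 1, 29 fatty acid, 74 oxidative phosphorylation, 18 tricarboxylic acid cycle and 13 regulator genes fell. Camera called all 4 lists, with adjusted p between 1.86e-32 and 4.20e-06. No call held with an estimated correlation (adjusted p = 0.204 with an estimated correlation for fatty acid genes, for oxidative phosphorylation and for regulators, and 0.263 for the tricarboxylic acid cycle).

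Among other energy genes the falls were fewer. Of 23 glycolysis and glucose uptake genes, 8 fell, 2 rose and 13 did not pass (median log2 fold change -0.11), with the same counts adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter, was at 0.691 of its sham level, Ldhb, a lactate dehydrogenase subunit, at 0.722 and Eno3, a muscle enolase, at 0.658, while Eno1, another enolase, and the lactate transporter Slc16a3 rose. Pfkfb1, a regulator of glycolytic flux, was among the 12 largest falls (log2 fold change -1.50 ± 0.20). With library totals only, 5 fell and 3 rose and the median was -0.01. This list had adjusted p = 0.011 by camera, and adjusted p = 0.288 with an estimated correlation. Of 13 mitochondrially encoded transcripts, 5 fell, none rose and 8 did not pass (median log2 fold change -0.24), and adjusted over the list alone 6 fell. Among those that fell, mt-Nd1 and mt-Co1 had log2 fold changes of -0.33 and -0.29. The calls of both ended in 3 of the 10 sets that left out a library (sham replicate 1, sham replicate 4 or TAC replicate 5), with replicate number as a block and with a correction for GC content and length. With library totals only, none of the 13 fell (median log2 fold change -0.14). Camera gave adjusted p = 0.00581, adjusted p = 0.514 with an estimated correlation, and adjusted p = 0.349 with a correction for GC content and length.

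The remaining large falls were spread over other functions. Timp4, a metalloproteinase inhibitor, was at 0.265 of its sham level (10.4 ± 4.1 to 2.79 ± 1.19 CPM), and Lgals4, a galectin, at 0.316. Acsm5, Dixdc1, Lrrc52 and Clcn1, a chloride channel of muscle, had log2 fold changes of -1.63, -1.57, -1.53 and -1.41. Tpd52l1, Ces3, a carboxylesterase, and Rgs2, a regulator of G protein signalling, had log2 fold changes of -1.24, -1.19 and -1.18. Pdk4, which inhibits pyruvate dehydrogenase, had 723 ± 934 CPM in sham and 233 ± 161 CPM in TAC and did not pass (adjusted p = 0.0664 by edgeR), although it was called lower without sham replicate 2 and without TAC replicate 2. Sham replicate 1 held 2391 CPM of it, against 230 to 349 in the other sham libraries.

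Macrophage genes rose. Of 23 tested macrophage and monocyte markers, 16 rose, none fell and 7 did not pass (median log2 fold change 0.75), with 16 adjusted over the list alone and 15 without the library labelled TAC replicate 1. The mean log2 CPM of the list was 4.47 in that library, 3.57 to 3.66 in the other TAC libraries and 2.99 to 3.24 in sham. C1qa and C1qc, chains of complement C1q, rose 1.62-fold and 1.68-fold, Itgam, an integrin of myeloid cells, 1.81-fold, and Aif1, a macrophage calcium-binding protein, 2.79-fold. By camera the adjusted p was 4.66e-06, and adjusted p = 0.288 with an estimated correlation. Interferon response genes also rose. Of 21 tested, 13 rose, none fell and 8 did not pass (median log2 fold change 0.85), and 17 rose adjusted over the list alone. Oas2, Irf9, Ifit2 and Bst2 rose 2.28-fold, 1.64-fold, 1.82-fold and 1.75-fold. Sham replicate 3 had a list mean of 3.11 log2 CPM, within the TAC range of 2.92 to 3.39, while the other sham libraries lay between 2.07 and 2.34. Camera gave adjusted p = 5.29e-07, and adjusted p = 0.288 with an estimated correlation.

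Endothelial markers rose in part. Of 20 tested, 9 rose, none fell and 11 did not pass (median log2 fold change 0.19), with the same counts adjusted over the list alone, and 12 rose with library totals only (median log2 fold change 0.29). Apln, apelin, rose 2.56-fold, Cdh5, VE-cadherin, 1.46-fold, Erg, an endothelial transcription factor, 1.41-fold and Pecam1 1.21-fold. This list had adjusted p = 0.00382 by camera, and adjusted p = 0.288 with an estimated correlation. Of 14 smooth muscle and pericyte markers, 3 rose, none fell and 11 did not pass, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.576). Its median log2 fold change (-0.03) and its mean (0.03) differed in sign, and the median was 0.08 with library totals only. The members that rose were Cspg4, Notch3 and Pdgfrb, which mark pericytes, by 0.63, 0.33 and 0.26 on the log2 scale. Other pericyte markers of the list, Rgs5, Kcnj8 and Abcc9, did not pass. Abcc9 had a log2 fold change of -0.27 ± 0.12 (adjusted p = 0.108 by edgeR).

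**Figure D3:**
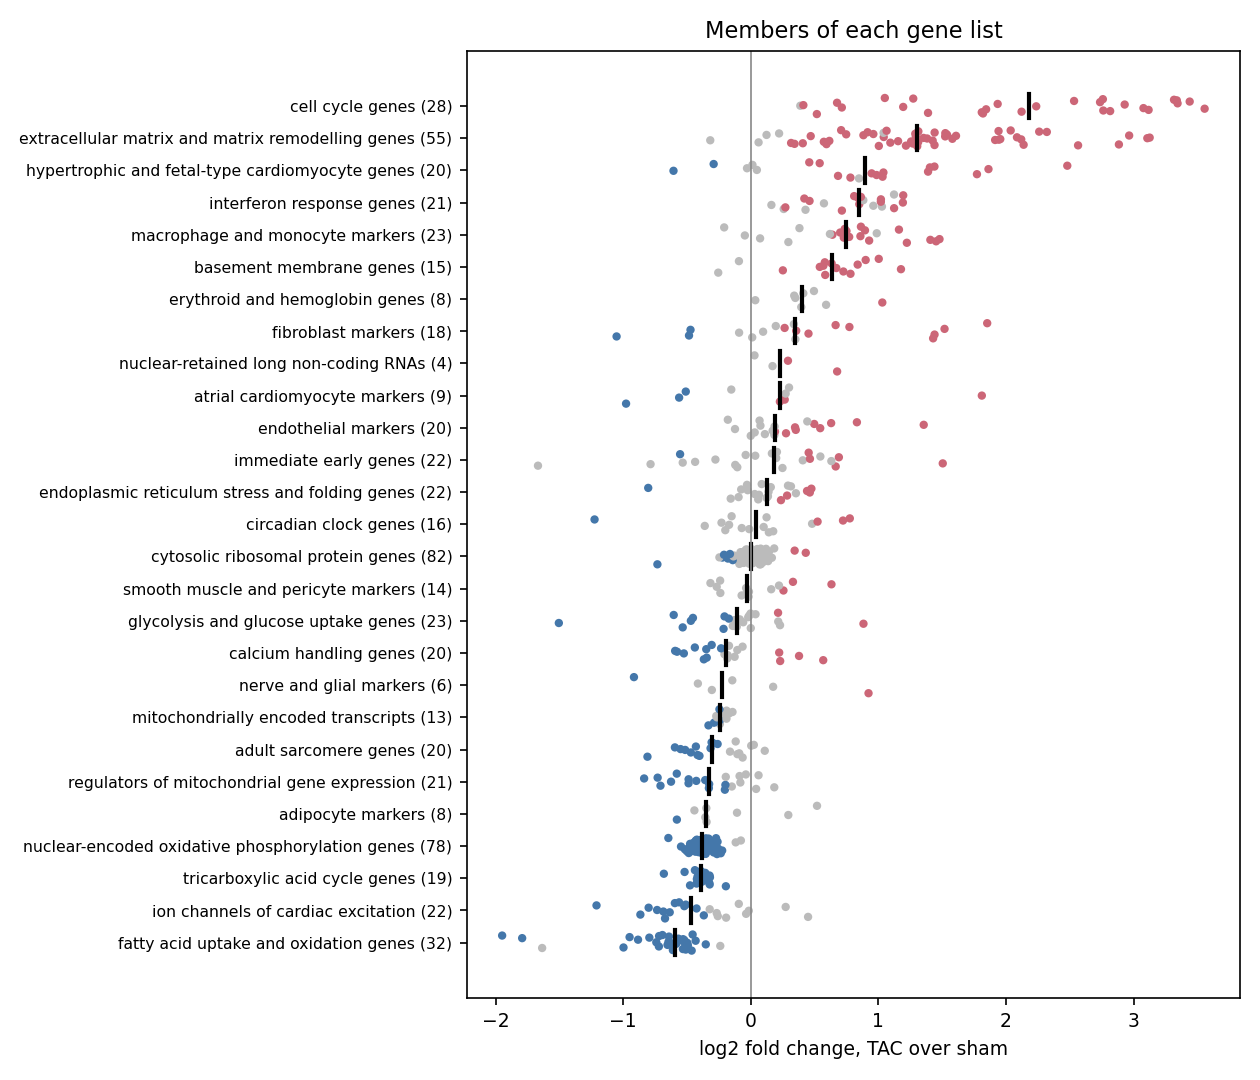
Log2 fold change, TAC over sham, of each tested member of the 27 gene lists with at least 3 tested members. Points are genes, red where they rose, blue where they fell and grey where they did not pass an adjusted p of 0.05; black bars are list medians, from 2.18 for cell cycle genes to -0.60 for fatty acid genes, and numbers in brackets are members tested.

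With the settings used, the other lists were not called by camera. Immediate early genes had 5 of 22 higher and 1, Zfp36, lower, and 5 higher and none lower adjusted over the list alone, or 4 higher and none lower without the library labelled TAC replicate 1 (adjusted p = 0.345). Myc rose 2.84-fold and Junb 1.37-fold, whereas Fos, Jun and Egr1 did not pass. Endoplasmic reticulum stress and folding genes had 5 of 22 higher, among them Pdia3, 1.39-fold, and 1, Herpud1, lower, with the same counts adjusted over the list alone (adjusted p = 0.184), and 10 higher with library totals only. Circadian clock genes had 3 of 16 higher, Bhlhe41, Wee1 and Per2, and 1 lower, and 3 higher and none lower adjusted over the list alone (adjusted p = 0.925). The lower gene, Arntl, had a log2 fold change of -1.22 ± 0.45 (adjusted p = 0.0487 by edgeR), and its call ended in 7 of the 10 sets that left out a library and with library totals only, DESeq2, robust dispersion estimates or a correction for GC content and length. Cytosolic ribosomal protein genes had 2 of 82 higher and 6 lower, and 1 higher and 2 lower adjusted over the list alone (median log2 fold change 0.00, adjusted p = 0.71). With library totals only, 23 were higher and 1 lower. With a correction for GC content and length, camera called the list upward (adjusted p = 0.00898, median log2 fold change 0.10), and the cause was not tested. Rpl3 rose 1.35-fold and its muscle paralogue Rpl3l was at 0.602 of its sham level. Atrial markers had 3 of 9 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.654), with a positive median log2 fold change (0.23), against the downward direction of the test. Dkk3 rose 3.51-fold and Tbx5, a cardiac transcription factor, was at 0.508 of its sham level. Erythroid and hemoglobin genes had 1 of 8 higher, and none adjusted over the list alone (adjusted p = 0.281). Adipocyte markers had 1 of 8 lower, Plin4 (adjusted p = 0.293), nerve and glial markers 1 of 6 higher, Ngfr, and 1 lower, Kcna1 (adjusted p = 0.559), and nuclear-retained long non-coding RNAs 2 of 4 higher, Meg3 and Gas5 (adjusted p = 0.293), each with the same counts adjusted over the list alone. The call of Gas5 ended in 6 of the 10 sets that left out a library, among them that without the library labelled TAC replicate 1, and the call of Ngfr ended without TAC replicate 3, without TAC replicate 4 and with limma-voom. Xist did not pass with all libraries (log2 fold change 0.03 ± 0.56, adjusted p = 0.977 by edgeR), but was higher in TAC without the library labelled TAC replicate 1 (log2 fold change 0.35, adjusted p = 0.000546 by edgeR). Of the lymphocyte and neutrophil markers only 2 each could be tested, and of these Cd4 and Csf3r rose, by 1.11 and 0.90 on the log2 scale. Of the 4 Y-linked genes none could be tested.

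Among library values other than gene levels, the shares of counts in the 10 highest genes and in ribosomal protein genes differed between the groups. The share of counts in the 10 highest genes was 15.7% ± 0.547 (SD, n = 5) in sham and 14.0% ± 0.934 in TAC (exact two-sided permutation test, p = 0.0159). Ribosomal protein genes took 1.48% ± 0.0171 of counts in sham and 1.59% ± 0.103 in TAC (exact permutation test, p = 0.0476), a difference that did not pass in 9 of the 10 sets that left out a library. The share in mitochondrially encoded transcripts was 9.42% ± 0.829 in sham and 8.55% ± 0.677 in TAC (exact permutation test, p = 0.127), and that in hemoglobin genes 0.0996% ± 0.0484 and 0.141% ± 0.0465 (exact permutation test, p = 0.222). Sham libraries had at least 1 count in a mean of 14788 genes and TAC libraries in 14926 (exact permutation test, p = 0.0556).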

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

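The tests on the library labelled TAC replicate 1, those on the metabolic genes, that of a shift alike in every TAC library and that on single gene lists were chosen after the results were seen, and the bound of the shift test was amended after its result, which under the first bound counted against that explanation; the test on single-exon genes and the splits for genes and for the number of lists were chosen before.

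The library labelled TAC replicate 1 lies farthest from sham and carries 155 counts of Ddx3y, 132 of Eif2s3y, 96 of Kdm5d (Jarid1d) and 42 of Uty, Y-linked genes with 0, at most 2, 0 and at most 3 counts in the other 9 libraries. A swap with a sham library is argued against by its slope of 1.301 along the effect of the other 4 TAC libraries, where the sham libraries lie between -0.04 and 0.16, and a mixture of male and female RNA by its Xist level, 0.987% of the mean of those 4 libraries. A lower share of cardiomyocyte RNA that raises all other cell types alike is argued against by their markers. These differ from the other TAC libraries by a median of 0.82 (log2) for macrophages and -0.23 for endothelium, a gap of 1.05 with a standard error of 0.174. That SE is over the members of both lists in 1 library. It takes the genes as independent and measures no spread between animals. A lower share with more RNA of only some cell types was not tested. Adult sarcomere genes lay lower in this library, by a mean of -0.198 ± 0.0412 (log2, SE over 20 members), which such a share could also give. The Xist and Y-linked counts argue against RNA of a female animal in this library, and how it came under a female label is not known. A stronger macrophage and matrix response in this heart stays open, since it rests on 1 library, and cannot be told apart from a difference by sex.

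Genes of fatty acid oxidation and oxidative phosphorylation fell. A lower share of cardiomyocyte RNA in the TAC libraries, as the whole cause, would lower sarcomere genes as much. This holds only if sarcomere genes kept their level within cardiomyocytes, which was not tested. The per-library mean of fatty acid genes minus that of sarcomere genes was lower in TAC by -0.384 (log2, exact permutation p = 0.00794, the smallest possible). For oxidative phosphorylation genes that difference was lower by -0.0893 (exact permutation p = 0.00794). A rise of sarcomere genes within cardiomyocytes, beside a lower share, could also give such differences. The mean log2 fold change was -0.71 for fatty acid, -0.38 for oxidative phosphorylation and -0.29 for sarcomere genes, so most of the fall of oxidative phosphorylation genes, and part of that of fatty acid genes, is not separated from such a share. The size of the fatty acid difference leans on single libraries. The mean log2 CPM of these genes was 8.66 in sham replicate 1, against 8.04 to 8.26 in the other sham libraries. It was lowest, 7.21, in the library labelled TAC replicate 1. That difference without both was not computed. Without sham replicate 1 alone, the median log2 fold change was -0.514 for fatty acid and -0.305 for sarcomere genes. Without TAC replicate 1 alone, these were -0.537 and -0.257. The composition factor of the normalization is argued against by the median log2 fold change of the fatty acid list with library totals only, -0.493. For the further fall of fatty acid genes, a lower level within cardiomyocytes of the loaded heart may be the source, as a hypothesis found and tested on the same libraries, and the differing stated processing of the groups stays open.

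Over 35% of the tested genes were called between groups whose stated aligner versions and genome builds differ. Misplaced reads across splice junctions, as the source of most calls, are argued against. Of 567 single-exon genes, 197 were called, 34.7% (95% Clopper-Pearson interval 30.8% to 38.8%), against 33.7% of multi-exon genes of the same mean expression, a ratio of 1.03. Whether such reads made a smaller part of the calls was not tested, since genes changed by the operation would be called in both kinds. A shift alike in every TAC library cannot be told apart from the operation: the slopes of the TAC libraries ranged 2.78 times as widely as those of the sham libraries, but 1.61 times without the library labelled TAC replicate 1. For the number of genes, chance is argued against: 4291 were called, and 1 of 100 splits (of 126 possible), the real one, reached that number. The highest of the other splits called 1. These other splits mix sham and TAC libraries, so their counts do not show what libraries without a group difference would give. Chance cannot be excluded for the number of lists (9 of 100 splits called at least 17, highest of the others 19). The 8 others all set 4 libraries of a group against 1, which keeps much of the real contrast, and the 77 splits of 3 against 2 called at most 16. For single lists, under 5% of the splits gave as small a camera p in 7 of the 17 and as large an absolute median in 16 of the 17, all but the endothelial list. Chance is argued against on both measures in 7, without adjustment over the 17 lists and with the same mixed splits.

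A library far from the others of its group was sought in 354 groups of 5, by its gap to the nearest library divided by the range of the group (Dixon's 95% value, 0.71). For genes and list means the ratio was taken on log2 CPM, whereas the gene values in brackets below are CPM. There were 28, 7.91%, where chance gives about 5%, with 10 in the library labelled TAC replicate 1 and 8 in sham replicate 1. In the library labelled TAC replicate 1 the ratios were 0.98 for Xist (1.62 CPM against 158 to 174), 0.898 for the macrophage list mean, 0.882 for the nuclear-retained RNA list mean, which holds Xist, 0.836 for Col3a1 (3054 CPM against 1053 to 1254), 0.82 for Col1a1, 0.827 for C1qa, 0.809 for C1qc, 0.796 for Rpl3l, 0.779 for Itgam and 0.718 for Eno3. In sham replicate 1 they include 0.822 for Pdk4, 0.808 for Erg, 0.746 for Meg3, 0.737 for Pdia4, 0.737 for Pparg (14.3 CPM against 8.58 to 9.82), 0.736 for Kcna1 and 0.733 for Ccna2. In sham replicate 2 they were 0.818 for the share of the 10 highest genes, 0.807 for the smooth muscle list mean, 0.781 for Herpud1 and 0.721 for Alas2. In TAC replicate 2 they were 0.863 for Ckap2l, 0.79 for Arntl and 0.749 for Bub1b. The rest were 0.778 for Itgam in sham replicate 5, 0.75 for the endoplasmic reticulum list mean in TAC replicate 5 and 0.738 for the interferon list mean in sham replicate 3.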

How the results depend on the processing

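All alternatives were chosen before the data were examined, except the distance and the list counts without the library labelled TAC replicate 1. Over the alternatives for single genes, 2990 of 3157 results of 144 named genes kept their side of the threshold, 153 were no longer called, 11 became called and 3 reversed. Of the 153, 87 came from the minimum fold of 1.5. A reversal was counted only where the gene was called in the main test or in the alternative. Uncalled genes that changed direction, such as Myh7 without the library labelled TAC replicate 1 (log2 fold change -0.07), are among the 2990. Genes higher ranged from 1876 to 2186 and genes lower from 1713 to 1975 when 1 library was left out. Against 2251 higher and 2040 lower, library totals only gave 1159 lower, and a minimum fold of 1.5 gave 238 higher and 19 lower, since that test asks for more than a difference. The distance between groups, 18.4, ranged from 17 to 20.4. Replicate numbers as a block gave 2113 higher and 1924 lower. Deviations of libraries with the same number correlated by -0.0916 to 0.222, and only sham replicate 4 correlated best with the TAC library of its own number. A pairing by number was thus neither shown nor excluded. With the correction for GC content and length, the mitochondrially encoded list was no longer called (camera adjusted p = 0.349), the ribosomal list was called upward (camera adjusted p = 0.00898), and mt-Atp8, mt-Nd4l and Rps27 turned to log2 fold changes of 0.0648, 0.00531 and 0.0155, none called; the cause was not tested. With an estimated correlation no list was called by camera: adjusted p = 0.126 for cell cycle and basement membrane, 0.20 for extracellular matrix, 0.204 for ion channels, fatty acid, oxidative phosphorylation, mitochondrial regulators and fibroblasts, 0.263 for hypertrophic genes and the tricarboxylic acid cycle, 0.276 for sarcomere, 0.288 for macrophages, glycolysis, endothelium and interferon, 0.385 for calcium handling and 0.514 for mitochondrially encoded transcripts. Apart from that setting, 562 of 565 list results were kept. The nuclear-retained RNA list was called without the library labelled TAC replicate 1 (camera adjusted p = 0.0341, with Xist, a member, then also called higher; 0.0341 to 0.361 over the sets that left out a library). Leaving out a library, the difference in genes with a count ranged from 111 to 173, passing without sham replicate 1 and without TAC replicate 2, and that in the ribosomal protein share from 0.0813 to 0.142 percentage points, passing only without TAC replicate 4. At this depth the test on simulated data, with only 200 genes changed, recovered 68.7% of 1.5-fold changes.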

Other observations

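The 18 gene families below and the test on clock genes were chosen after the data were seen; the clock test was first judged against a bound of 1 pooled SD, under which the explanation counted as excluded, was then left out, and was restored with a bound narrowed to 0.5, under which it is undecided.

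Besides the lists above, 18 families defined by gene symbol were examined. Of 76 mitochondrial ribosome genes, 51 fell, none rose and 25 did not pass (median log2 fold change -0.28; 32 fell with library totals only). Of 36 mitochondrial carrier genes, 15 fell and 2 rose (11 and 6 with library totals only). Among them Slc25a4, the adenine nucleotide carrier, and Slc25a20, the carnitine carrier, fell. Of 15 peroxisomal biogenesis genes, 5 fell and none rose (4 fell with library totals only). Of 22 integrin genes, 12 rose and none fell, among them Itgav, Itga5, Itgb1 and Itga11, which encode receptors for matrix. Of 15 serpin genes, 7 rose and none fell, and of 9 syndecan and glypican genes 5 rose and none fell. Of 11 tubulin genes, 8 rose and 2, Tuba8 and Tuba4a, fell. Of 9 annexin genes, 6 rose and 1, Anxa11, fell, and of 8 S100 genes 5 rose and 1, S100a1, fell (none with library totals only). Of 30 kinesin genes, 15 rose and 5 fell (18 and 2 with library totals only), those that rose including Kif23, Kif20a and Kif2c, which act in cell division. Of 33 ADAM and ADAMTS genes, 13 rose and 3 fell (14 and 2 with library totals only), and of 11 cathepsin genes 6 rose and 2 fell (6 and 1 with library totals only).

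Of 37 proteasome genes, 9 fell and 1, the immunoproteasome gene Psmb8, rose, but with library totals only none fell and 2 rose. Of 54 genes with the symbol of translation initiation factors (Eif), 9 fell and 5 rose, and 2 and 11 with library totals only. The symbol also takes in kinases and binding proteins of these factors. Of these, Eif2ak2, Eif2ak3 and Eif4ebp1 were among the genes that rose, and Eif2ak1 and Eif4enif1 among those that fell. Of 26 semaphorin and plexin genes, 7 rose and 5 fell, and 14 and 3 with library totals only. Of 7 replication-dependent histone genes, 1 rose and 2 fell. Of 18 aminoacyl-tRNA synthetase genes, 1 rose and 1 fell (2 and none with library totals only), and 8 chaperonin genes had a median log2 fold change of -0.01 (0.09, with 2 that rose, with library totals only). With an estimated correlation camera called no family (lowest adjusted p = 0.154).

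Arntl was lower and Per2 and Wee1 higher in TAC, and a difference in the time of day at which the groups were collected may shift clock genes that way. The test took the per-library mean log2 CPM of 8 genes (Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1 and Nr1d2) minus that of Arntl, Npas2 and Clock. It was 2.75 ± 0.852 (SD, n = 5) in sham and 3.51 ± 0.749 in TAC, a difference of 0.761 (exact permutation p = 0.175) against a pooled SD of 0.802. The hypothesis was not decided: the difference did not pass, and it was too large beside the spread to be excluded.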
